A study of Rattus norvegicus with 18 samples.

How the data were processed

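Abdominal aorta of 18 rats was profiled by RNA sequencing of ribosomal RNA-depleted libraries, per the labels' protocols. The rats formed 3 groups of 6. WKY (Wistar Kyoto) is the normotensive strain used as the control of SHR, the spontaneously hypertensive rat, an inbred strain with inherited high blood pressure. SHR+ETH denotes SHR given ethoxysanguinarine, a plant alkaloid, by gavage at 3.5 mg/kg per day for 10 weeks, and the WKY and SHR groups received water. Per the treatment protocol, the SHR were allocated at random to water or ethoxysanguinarine, so replicates are separate animals. Libraries are named here by group and by the number in their labels. The labels of the SHR+ETH group carry both water and ETH as treatment, and the group label was used. The numbers 1 and 2 occur in both WKY and SHR+ETH but belong to different animals of different strains.

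Each deposited table gave 1 non-negative signal value per transcript, with no unit named in the file headers. The submitters' processing notes name limma, without a version. The aligner, the quantification program, the genome build, the assembly of transcripts and any filter are not given in the sources used here. The values were fractional. Low values were compared with whole multiples of a step, with a tolerance of 0.1 steps over the first 20 steps, and at most 28.4% of the values in a library were whole, so read counts were not recovered and the depth of each library is unknown. No counting interval or detection floor can therefore be given, and a transcript without signal is described as listed at 0. Sums of values are sums over the listed transcripts, not library sizes.

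The files held part of a transcriptome. The 6 WKY and 6 SHR tables listed the same 3659 transcripts, the 6 SHR+ETH tables listed another set of 1635, and 420 were in both. Each SHR+ETH table also had 2024 rows without identifier or value, which were left out. Identifiers were Ensembl transcripts (ENSRNOT numbers) or transcripts of a merged assembly (MERGE numbers). The lowest mean over the 12 WKY and SHR libraries was 0.250 in the strain list. Among the 420 shared transcripts the lowest mean was 0.255 over WKY and SHR and 0.255 over SHR and SHR+ETH, whereas 80 had a mean under 0.25 over WKY and SHR+ETH. A lower limit near 0.25 was thus seen for each of the 2 comparisons that involve SHR and not for the third. Of the transcripts tested between SHR and WKY, 85.7% had an unadjusted p under 0.05. A list that had been chosen for a difference would show such a share, and the criterion is not given in the sources used here. Adjusted p-values below cover only the listed transcripts that passed the filter, so counts of calls are counts within those lists and not rates over the aortic transcriptome. If the lists were chosen for differences in these same libraries, the adjusted p-values are too small. They would then not hold false calls to the stated rate.

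Transcripts with a value of at least 1 in at least 6 of the 12 libraries of the 2 groups compared were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on log2(value + 1), with group as the only term. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. All p-values are two-sided, except the permutation p for loci, which is one-sided. Fold changes are on the log2(value + 1) scale, which understates changes of low transcripts. Because the lists differed, each comparison was fitted on its own 12 libraries. Both comparisons with SHR+ETH used the 420 shared transcripts, and the other 1215 of its list had no values in the other groups and entered no comparison. Single values per library were compared by exact permutation tests, for which 6 against 6 allows no p below 0.00216, and shares by Fisher's exact test. The latter treats transcripts of the same libraries as independent. The tests of single library values and of transcript classes were chosen after the values were seen. The limma comparisons, the analysis of opposite signs and the alternatives, other than those said to be added later, were fixed before the data were examined. The tests of selection on the SHR libraries, unstable estimates, loci and splits for SHR+ETH against WKY were fixed before their own results were seen. The comparison of called shares and the overlap with independent lists were not fixed beforehand. Summaries were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

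The limma step was tested on simulated data with known changes. These were placed in 200 transcripts for SHR against WKY, 66 for SHR+ETH against SHR and 52 for SHR+ETH against WKY. For SHR against WKY (1585 transcripts) limma recovered 50.7%, 82.1% and 93.9% of transcripts changed by 1, 2 and 3 on the log2 scale, with 8 false calls. For SHR+ETH against SHR (199 transcripts) it recovered 45.5% of changes of 1 and all of those of 2 and 3, with 2 false calls. For SHR+ETH against WKY (157 transcripts) it recovered 33.3%, 76.5% and 88.2%, with 2 false calls. Among the real transcripts tested, 82.5%, 33.7% and 1.91% were called in these comparisons, in the same order. Whether the simulated values matched the skew of the real ones was not tested. The rates therefore describe the simulated setting and need not hold for the real lists.

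The files pair no identifier with a gene name. The gene table used for names (assembly GRCr8) matched 0 of the 1247 Ensembl transcripts listed, so the 31 gene lists fixed beforehand, among them TGF-beta and Smad signalling, collagens, contractile smooth muscle and cell type markers, had 0 members that could be named and their set tests were not run. The rule for named genes asked for symbols and could not be met. In its place, by a rule made after the files were seen, up to 2 higher and 2 lower Ensembl transcripts per comparison are named, those with the smallest p among called transcripts with a mean log2 value of at least 2. The 3 transcripts called between SHR+ETH and WKY and the most abundant transcripts fell outside that rule and were named after their values were seen.

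Both comparisons of SHR use the same SHR libraries, so opposite signs arise by chance. Groups without differences were simulated over the 420 shared transcripts in 100 sets, and the SHR libraries were also split into 2 sets of 3 that each served 1 comparison, in 20 ordered assignments. Alternatives were a pseudocount of 0.1, no filter, a stricter filter (at least 5 in at least 6 libraries), quantile normalization, limma without trend, library weights, an added threshold of an absolute log2 fold change above 1, each library left out, and the replicate number as a block for SHR+ETH against WKY. After the data were seen, a fit of all 18 libraries, a fit of SHR against WKY on the shared transcripts alone and quantile normalization for the count of opposite signs were added. For every comparison 100 of the 462 distinct splits of its 12 libraries were refitted, the real one included.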

Results

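Transcript levels in the abdominal aorta were compared between normotensive WKY rats, spontaneously hypertensive rats (SHR) and SHR treated with ethoxysanguinarine (SHR+ETH), with 6 animals per group. The tables for WKY and SHR gave values for 3659 transcripts, of which 957 had Ensembl identifiers and 2702 (73.8%) came from a merged assembly. Most levels were low: the median transcript had a mean value of 1.05, and 1761 transcripts (48.1%) had a mean under 1. The values of the listed transcripts summed to 39209 ± 7584 (SD, n = 6) per WKY library and 32412 ± 9423 per SHR library, a difference within the spread (exact permutation p = 0.193, adjusted 0.231 over 6 tests). The SHR+ETH tables gave 1635 other transcripts, 420 of them shared with the first list, and summed to between 7046 and 10220. No pair of libraries was identical. The depth behind the values is unknown. Over the 3659 transcripts the median rank correlation was 0.677 between WKY libraries, 0.658 between SHR libraries and 0.160 between a library of each strain. These are correlations across transcripts, which are not independent replicates, in a list that appears to have been chosen for strain differences.

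The strain comparison asks which aortic transcripts differ between hypertensive and normotensive rats. ENSRNOT00000002310 had a value of 17.2 ± 4.15 (SD, n = 6) in SHR and was listed at 0 in all 6 WKY libraries (limma adjusted p = 7.05e-09), so no fold is given. ENSRNOT00000003413 was higher in SHR, at 21.4 ± 3.92 against 1.41 ± 1.16 in WKY (log2 fold change 3.32, SE 0.32, adjusted p = 1.48e-06). In the other direction ENSRNOT00000031418 fell from 196.4 ± 64.1 in WKY to 5.28 ± 1.45 in SHR (log2 fold change -4.93, SE 0.32, adjusted p = 2.68e-08). ENSRNOT00000093669 fell from 16.5 ± 6.05 to 0.0859 ± 0.0657 (log2 fold change -3.94, SE 0.26, adjusted p = 3.31e-08). In each of these transcripts the 6 SHR values lay apart from the 6 WKY values.

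**Figure D1:**
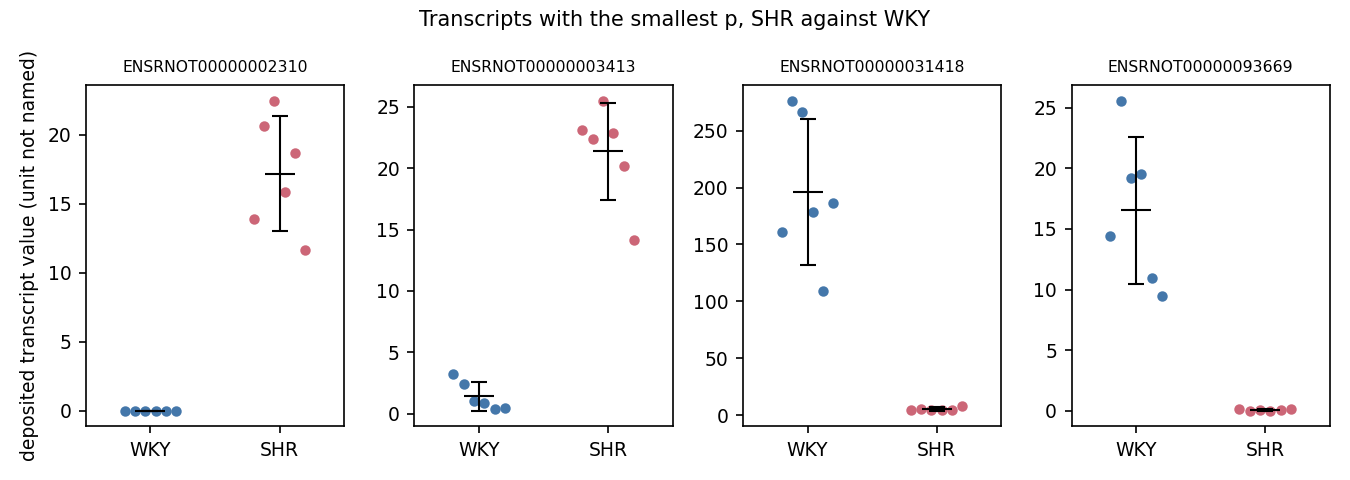
Deposited value (vertical axis, unit not named, a separate linear scale in each panel) of the 4 named transcripts in the 6 WKY and 6 SHR libraries. Points are libraries and bars are mean ± SD; ENSRNOT00000002310 and ENSRNOT00000003413 were higher in all 6 SHR libraries, and ENSRNOT00000031418 and ENSRNOT00000093669 were lower in all 6.

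Of 1585 listed transcripts tested, 1308 (82.5%) differed between the strains, with 704 higher in SHR (median log2 fold change 1.15, interquartile range 0.92 to 1.60) and 604 lower (median -1.17, -1.70 to -0.88). Quantile normalization gave 632 higher and 656 lower, so which direction was more frequent depended on the scaling. It gives all libraries the same distribution over the tested transcripts, which by construction reduces a shift common to the list. The balance of directions is thus unsettled. Among the called transcripts 857 had an absolute log2 fold change above 1, and in 384 the SHR and WKY values did not overlap. Such separation occurred in 24.3% of tested transcripts, against 0.216% by chance in an unselected list. A list chosen for strain differences would show such an excess, as real differences would, and these were not told apart. Ensembl transcripts were called in 486 of 582 cases (83.5%) and assembled transcripts in 822 of 1003 (82.0%), a difference that did not pass Fisher's exact test (p = 0.451, adjusted 0.451 over 3 tests). The share called describes the list and is not a rate over all aortic transcripts. The count was 2547 without the filter on low values, 380 with the stricter filter and 121 when only the 202 testable transcripts of both lists entered the fit.

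Some transcripts were listed at 0 throughout 1 strain. In all 6 WKY libraries 298 transcripts were at 0, and 75 of these (10 Ensembl and 65 assembled) were above 0 in all 6 SHR libraries. In all 6 SHR libraries 166 were at 0, and 66 of these (7 Ensembl and 59 assembled) were above 0 in all 6 WKY libraries. A WKY library had 883.5 ± 98.0 listed transcripts at 0 and an SHR library 656.2 ± 51.9 (SD, n = 6 each, exact permutation p = 0.00433, adjusted 0.00866 over 6 tests), a difference that holds for this list, which appears to have been chosen for strain differences. The 6 tests include those of SHR zeros among the shared transcripts, where the choice of list would itself give a small p. Their inclusion makes this adjusted value smaller. The most abundant transcript, ENSRNOT00000040993, took 28.6% to 53.9% of the listed signal in WKY libraries and 7.51% to 56.3% in SHR libraries. Its value was 16218 ± 6344 in WKY and 9504 ± 9757 in SHR, where it ranged 15.6-fold between libraries. A strain difference did not pass on the values themselves (exact permutation p = 0.186, adjusted 0.231). On the log scale it narrowly missed the threshold (log2 fold change -1.30, SE 0.58, limma adjusted p = 0.0501), so a difference is not excluded. ENSRNOT00000016540, another abundant transcript, fell from 2039 ± 838 in WKY to 698 ± 376 in SHR (log2 fold change -1.62, SE 0.41, limma adjusted p = 0.00518). ENSRNOT00000005872, also abundant, stood at 1190 ± 327 in SHR and 683 ± 827 in WKY, where it ranged from 0 in WKY 3 to 2209 in WKY 1, and did not pass (limma adjusted p = 0.0606).

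The treatment comparison asks what ethoxysanguinarine changed in the aorta of SHR, a study whose title names TGF-β1/Smad2/3 signalling. Members of that pathway could not be read out, because the identifiers came without gene names and the gene table used here matched none of the Ensembl identifiers. ENSRNOT00000018861 was higher in treated SHR, at 10.7 ± 3.37 (SD, n = 6) against 2.70 ± 2.20 in untreated SHR (log2 fold change 1.85, SE 0.50, limma adjusted p = 0.0284). ENSRNOT00000076987 was also higher, at 7.19 ± 3.15 against 2.75 ± 3.08 (1.42, SE 0.51, adjusted p = 0.0472). ENSRNOT00000010759 was lower, at 61.8 ± 119 against 211 ± 141 (-2.77, SE 0.90, adjusted p = 0.0426), and 1 treated animal, SHR+ETH 2, stood at 304 while the other 5 lay between 6.51 and 27.2. ENSRNOT00000084913 was lower on the log scale, at 24.5 ± 38.9 against 44.8 ± 25.8 (-2.89, SE 1.03, adjusted p = 0.0472). In it SHR+ETH 64 at 91.1 was the highest of the 12 libraries and SHR+ETH 1 stood at 53.5, while the other 4 treated animals lay between 0 and 1.64. None of these transcripts separated the groups fully. A pseudocount of 0.1 ended all 4 calls (adjusted p = 0.0623 each), leaving out the filter ended all but that of ENSRNOT00000018861 (adjusted p from 0.0552 to 0.0590), and quantile normalization ended those of ENSRNOT00000010759 and ENSRNOT00000084913 (adjusted p = 0.0521 and 0.0767). The fit of all 18 libraries ended that of ENSRNOT00000084913 (adjusted p = 0.0519). The call of ENSRNOT00000018861 was also lost without SHR 41 (log2 fold change 1.70, adjusted p = 0.0538). The call of ENSRNOT00000076987 was lost without any 1 of SHR+ETH 1, 2, 54 or 64 or SHR 3, 40, 41, 48 or 60 (log2 fold changes 1.18 to 1.54, adjusted p from 0.0522 to 0.0909). For ENSRNOT00000010759 the same held without SHR+ETH 64 or 65 or SHR 3, 40, 41, 48 or 59 (-3.06 to -2.45, adjusted p from 0.0525 to 0.0776). ENSRNOT00000084913 lost its call without SHR+ETH 2, 54, 58 or 65 or any 1 of the 6 SHR libraries (-3.08 to -2.41, adjusted p from 0.0529 to 0.0817).

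Among the 199 of the 420 shared transcripts that could be tested, 67 differed between SHR+ETH and SHR. In treated animals 17 were higher (median log2 fold change 1.42) and 50 lower (median -1.22). Quantile normalization turned this into 48 higher and 7 lower, and 24 transcripts were called both with and without it. That scaling moved the log2 fold changes of the tested transcripts by a median of 0.51. Their median was -0.85 before and -0.26 after it. Quantile normalization gives all libraries the same distribution over the 199 tested transcripts, of which 141 were lower in SHR+ETH before it. A shift common to such a list is reduced by construction, so the turn does not tell which balance is right. The balance of the directions is not settled by these data. At an unadjusted p under 0.05, 120 transcripts (60.3%) differed. A list chosen for differences from SHR in these libraries would show such a share. The calls and their adjusted p-values are therefore not independent evidence of a treatment effect. In 9 of the called transcripts the groups did not overlap. The count was 12 with a pseudocount of 0.1, 43 without the filter, 20 with the stricter filter and 37 in a fit of all 18 libraries. It also rested on single libraries, falling to 11 without SHR 41, 23 without SHR 48, 25 without SHR 3, 27 without SHR 40, 27 without SHR 60, 44 without SHR 59, 40 without SHR+ETH 65 and 44 without SHR+ETH 54.

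In the 420 transcripts listed for all groups, the changes between SHR+ETH and SHR ran opposite to those between SHR and WKY. Of 147 called between the strains, 143 (97.3%) had the opposite sign in the treatment comparison, including all 103 that were higher in SHR. The 50 transcripts called in both comparisons all had opposite signs, but 11 were called in both with a pseudocount of 0.1 and 1 to 3 (median 1) when separate SHR libraries, 3 in place of 6, served each comparison. With fewer libraries a median of 69 rather than 147 shared transcripts were called between the strains, so that drop cannot be assigned to the separation alone. Of 185 transcripts tested in both, 37 were called higher in SHR and lower in SHR+ETH where independent lists would share 25.2, and 13 were called the other way where they would share 2.84. Independence leaves out the shared SHR libraries, so these differences are not evidence of a shared effect. Over all 420 the signs were opposite in 414 (98.6%), and in 392 (93.3%) after quantile normalization. Without that scaling the correlation across transcripts was -0.925 with a covariance of -1.13. Both comparisons share the SHR libraries, and simulated groups without any difference gave a correlation of -0.504, a covariance of -0.113 and opposite signs in 66.7%. The difference of the covariances was -1.02. These simulated transcripts were not picked, whereas the 420 appear to have been listed for differences from SHR. The simulated values are therefore no baseline for the 420, and the difference is not evidence of a reversal. When simulated transcripts were picked for an unadjusted p under 0.05 in both comparisons, 99.3% had opposite signs, against 99.5% (211 of 212) in the data, so the share of opposite signs carries no information in transcripts picked this way. The simulation does not reproduce how many were picked, 3964 of 420000 simulated transcripts against 212 of 420 in the data. A list chosen for differences from SHR would also raise that number. With the SHR libraries split into 2 sets of 3, the median correlation was -0.79 (range -0.82 to -0.72 over 20 assignments), and 90.5% to 97.1% of the called transcripts had opposite signs, although the lists themselves appear to have been chosen with all 6 SHR libraries.

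**Figure D2:**
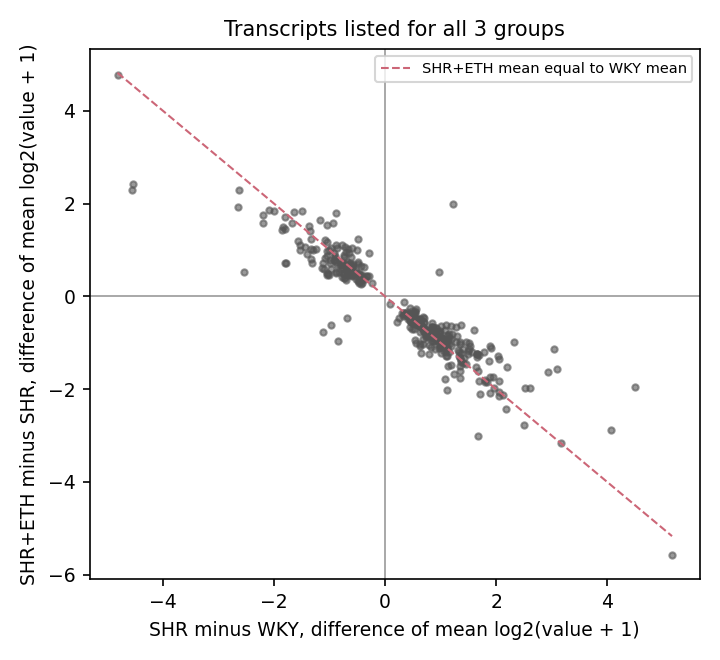
Differences of mean log2(value + 1) for the 420 transcripts listed in all groups, SHR minus WKY on the horizontal axis and SHR+ETH minus SHR on the vertical axis, each point being 1 transcript. The dashed line marks equal means in SHR+ETH and WKY; 414 points have opposite signs on the axes.

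The 274 shared transcripts that were higher in SHR had a mean log2(value + 1) of 0.70 ± 0.11 per library in WKY, 1.74 ± 0.13 in SHR and 0.80 ± 0.11 in SHR+ETH (SD, n = 6 each). The 146 that were lower in SHR stood at 1.70 ± 0.10, 0.71 ± 0.07 and 1.53 ± 0.09. SHR+ETH minus WKY was 0.10 in the first set and -0.17 in the second. After quantile normalization the first set stood at 0.78 ± 0.07 in WKY, 1.48 ± 0.03 in SHR and 0.88 ± 0.04 in SHR+ETH, and the second at 1.83 ± 0.12, 0.56 ± 0.07 and 1.66 ± 0.06. Because the 2 sets were formed by the sign of SHR minus WKY, chance values of both SHR and WKY entered that choice, so the distances of SHR+ETH from either group are given without a test. A library had 134.2 ± 16.5 of the 420 at 0 in WKY, 70.2 ± 7.31 in SHR and 125.5 ± 14.1 in SHR+ETH. The lower number in SHR is given as a value only, since a list chosen for differences from SHR, with 274 of 420 higher there, would show it. SHR+ETH and WKY did not differ beyond the spread (exact permutation p = 0.387, adjusted 0.387 over 6 tests). Across the 420 transcripts the median rank correlation was 0.531 between an SHR+ETH and a WKY library, 0.204 between SHR+ETH and SHR, and 0.125 between SHR and WKY. A list chosen for differences of SHR from both other groups would itself give low correlations with SHR, so these values do not measure how alike the groups are.

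**Figure D3:**
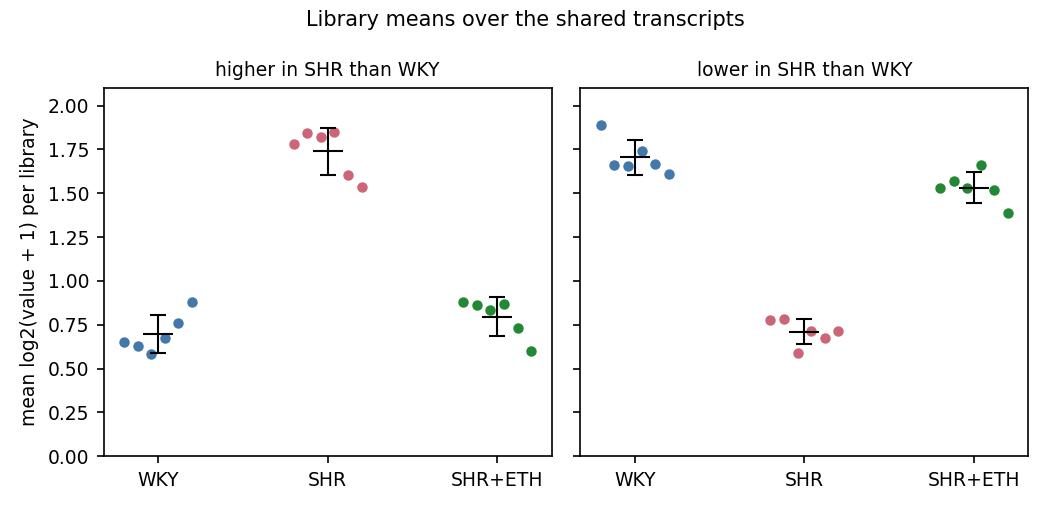
Mean log2(value + 1) per library over the 274 shared transcripts higher in SHR than WKY (left) and the 146 lower (right), in the 3 groups of 6. Points are libraries and bars are mean ± SD. SHR+ETH libraries lie closer to WKY than to SHR in both panels, for transcripts listed in both tables and sorted by their SHR difference. In the right panel all SHR+ETH libraries but SHR+ETH 58 lie below the lowest WKY library.

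The third comparison asks how far treated SHR stood from the normotensive strain. Of 157 shared transcripts tested, 3 differed between SHR+ETH and WKY, and 10 (6.37%) had an unadjusted p under 0.05. MERGE.27009.4 was lower in SHR+ETH, at 0.0533 ± 0.103 against 2.25 ± 0.896 (SD, n = 6, log2 fold change -1.58, SE 0.22, limma adjusted p = 0.00120), with 0.672 ± 0.585 in SHR. It was listed at 0 in 4 of the 6 SHR+ETH libraries, so the size of this fold depends on the pseudocount. MERGE.19062.61 was higher, at 15.4 ± 20.3 against values listed at 0 in 5 of the 6 WKY libraries and 0.00335 in the other (adjusted p = 0.0118), so no fold is given, with 5.46 ± 11.9 in SHR. ENSRNOT00000011880 was lower, at 1.26 ± 1.55 against 6.00 ± 1.83 (-1.88, SE 0.42, adjusted p = 0.0347), with 2.19 ± 0.630 in SHR. In all 3 transcripts the SHR+ETH and WKY values did not overlap. The call of ENSRNOT00000011880 was lost without any 1 of SHR+ETH 1, 64 or 65 or WKY 1, 2, 4, 5 or 6 (-1.97 to -1.70, adjusted p from 0.0503 to 0.0957). Without the filter on low values the count was 1, with adjusted p = 0.0532 for MERGE.19062.61 and 0.117 for ENSRNOT00000011880, and a pseudocount of 0.1 ended the call of the latter (adjusted p = 0.156). The count was 6 in a fit of all 18 libraries. With the stricter filter limma called 0 of 39, of which 1 had an unadjusted p under 0.05. The shared transcripts appear to have been listed for differences from SHR, so the low count says nothing of transcripts outside the list. Within the list, such a choice would itself tend to place SHR+ETH and WKY on the same side of SHR. The low count therefore does not measure how alike SHR+ETH and WKY are.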

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

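The tests of the pattern weighed here were chosen before their results were seen, but the reason given for leaving the first open was added afterwards. Of 47 groups of 6 values examined, 10 held a library set apart from the other 5 by a gap test. Chance gives about 1 in 20 groups for normally distributed values, but these values were skewed and many were 0, so the number of such groups is not read as an excess. ENSRNOT00000040993 reached 28192 in SHR 60, with the other SHR libraries between 1812 and 10186. SHR+ETH 65 had 547 of its listed transcripts at 0, against 416 to 450 in the other treated animals, and 153 of the 420 shared transcripts at 0, against 112 to 123. ENSRNOT00000010759 stood at 303.8 in SHR+ETH 2, with the others between 6.51 and 27.2. ENSRNOT00000084913 stood at 50.5 in WKY 2, with the others between 0 and 1.23. MERGE.27009.4 was high in SHR 59 (1.79, others 0.207 to 0.678) and in SHR+ETH 2 (0.256, others 0 to 0.0633). MERGE.19062.61 stood at 0.00335 in WKY 5 with the others at 0, where any value above 0 would stand apart, at 29.6 in SHR 3 (others 0 to 2.74) and at 54.4 in SHR+ETH 54 (others 1.83 to 20.5).

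The pattern that a reader would most want to follow is the opposite direction of the strain and treatment differences in the shared transcripts. A candidate explanation is selection on the shared SHR libraries: a transcript whose 6 SHR values lie off by chance is picked in both comparisons and then points in opposite directions. Simulated unchanged groups gave opposite signs in 99.3% of transcripts picked in this way, although 3964 of 420000 were picked there against 212 of 420 in the data. Among transcripts with p under 0.05 in both comparisons, 9.91% (21 of 212) had p under 0.005 in both, above the 3.71% of the simulation. That share also lay above 6.60%, the upper limit of the central 95% range of binomial draws. Those draws took 212 independent transcripts at the simulated share. That excess argues against the simulated setting as a whole, yet it does not exclude the explanation, because the simulation treated transcripts as independent and left out real strain differences and the unknown criteria by which the lists were made. Unstable transcript estimates may add to the pattern: 243 of the 420 shared transcripts (57.9%) were at 0 in 1 library and at 1 or more in another library of the same group, counting WKY and SHR libraries alone for both sets, against 1194 of the other 3239 (36.9%), a difference of 21.0 points (95% interval 16.0 to 26.0, Fisher's exact test p = 3.39e-16). That p and interval treat transcripts of the same libraries as independent. Whether unstable transcripts carry the opposite signs was not tested, and with 414 of the 420 opposite there is little to compare. An effect of ethoxysanguinarine on these transcripts stays open as untested, since no list chosen without the SHR libraries was analysed here.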

How the results depend on the processing

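The fits of all 18 libraries and of the shared transcripts alone, and the opposite signs under quantile normalization, were chosen after the data were seen; the other settings were planned. For SHR against WKY the count of 1308 became 2547 without a filter, 380 with the stricter filter, 857 with an absolute log2 fold change above 1 and 121 on the shared transcripts, and stayed between 1102 and 1229 with a library left out. For SHR+ETH against SHR the count of 67 became 12 with a pseudocount of 0.1, 43 without a filter, 20 with the stricter filter, 37 with all 18 libraries, and 11 to 71 with a library left out. For SHR+ETH against WKY the count of 3 became 1 without a filter, 0 with the stricter filter (1 of 39 at an unadjusted p under 0.05), 6 with all 18 libraries, and 2 to 4 with a library left out. With the number in the labels as a replicate block, limma called 0 of 157 (10 at an unadjusted p under 0.05); only the numbers 1 and 2 occur in both groups, and they name unrelated animals, so this is not a paired design. Changes under the filters follow in part from the number of transcripts tested; otherwise the cause was not tested. Among shared transcripts called between the strains, the share of opposite signs was 97.3%, and 98.5% without a filter, 97.3% with a pseudocount of 0.1, 97.2% with quantile normalization and 94.8% with the SHR libraries split. Over all 420 shared transcripts it fell from 98.6% to 93.3% with quantile normalization. Of 215 recomputed fold changes of named transcripts 164 kept their call, 51 lost it and 0 reversed. The 4 named transcripts of SHR against WKY kept their calls in all 19 settings each, but they had the smallest p in a list that appears chosen for that difference. Calls between SHR+ETH and SHR were kept less often. ENSRNOT00000018861 kept its call in 18 of 20 settings and ENSRNOT00000076987 in 8 of 19. ENSRNOT00000010759 kept it in 10 of 20 and ENSRNOT00000084913 in 6 of 20. The planned fit of 12 libraries is the one reported. The gene set alternatives were not run because the gene table used here matched none of the Ensembl identifiers. With the depth unknown, values at 0 cannot be given a limit.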

Other observations

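In this part the split tests of SHR against WKY and of SHR+ETH against SHR and the tests of transcript class were chosen after the results were seen. The test of called shares was not fixed beforehand. The treated animals had 1215 listed transcripts without values in the other groups. Of these, 623 were above 0 and 204 were at 1 or more in all 6 SHR+ETH libraries, while 97 were at 0 in all 6. The most abundant was ENSRNOT00000029791, at 1018 ± 338 (SD, n = 6). They can be compared with no control.

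Transcripts at 0 in all libraries of 1 strain and above 0 in all of the other were assembled transcripts in 124 of 141 cases (87.9%), against 2578 of the other 3518 (73.3%, Fisher's exact test p = 5.09e-05, adjusted 8.60e-05 over 3 tests). The shared transcripts were less often called between the strains, in 147 of 202 (72.8%) against 1161 of 1383 (83.9%, Fisher's exact test p = 0.000216), and were more often higher in SHR, in 136 of 202 (67.3%) against 722 of 1383 (52.2%, p = 5.74e-05, adjusted 8.60e-05).

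The 2702 assembled transcripts came from 2169 loci, read from the shared part of their identifiers, and the largest locus had 32. At 65 loci 2 or more assembled transcripts were called between the strains, and at 30 (46.2%) they went in both directions, against 35.9 loci when directions were permuted (one-sided permutation p = 0.0765 for as few). Loci with both directions were thus not in excess. A hypothesis is that reads were traded between transcripts of a locus, which would make opposite transcripts deviate against each other within a group. The median within-group correlation of such pairs was 0.000232 (95% interval -0.191 to 0.092 over loci), with random pairs of opposite direction at -0.227 to 0.167 in 1000 sets. The interval is too wide to exclude a negative correlation, so this possible explanation cannot be told apart from its absence. The bound set beforehand asked only for a median above -0.120, which was met, and the interval was added after that result was seen.

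Splits of the 12 libraries of each comparison were refitted 100 times, the real split included. For SHR against WKY only the real split, 1 of 100, reached 1308 transcripts, and the highest other had 242. For SHR+ETH against SHR only the real split, 1 of 100, reached 67, and the highest other had 6. Neither bears on chance, because the lists appear to have been chosen for these very splits. For SHR+ETH against WKY 2 of 100 splits gave 3 or more transcripts, the real one included, and the highest other gave 4, which is more than the real count. By unadjusted p the same comparison had 10 transcripts, the highest other split 17, and 27 of 100 splits as many. Few splits reached the count of calls, but since 1 exceeded it and the unadjusted count was common among splits, chance is not excluded for this comparison as a whole.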
